A study of Mus musculus with 9 samples.

How the data were processed

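Gene expression was measured in whole cochleae of male C57BL/6 mice on 9 arrays of 1 colour each. Per the labels, 3 arrays carried 4-month-old controls (YC), 3 carried 15-month-old controls (MC) and 3 carried 15-month-old mice on calorie restriction (CR). The restricted mice received 62 kcal per week against 84 in controls, a 26% reduction, from 2 months of age until 15 months. Each sample pooled 4 cochleae of 2 mice, and the series text describes 3 such samples per group without technical replicates or dye swaps.

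Total RNA was extracted with TRIzol, and biotin-labelled cRNA was made with an in vitro transcription kit following Affymetrix instructions, per the labels' protocols. The submitters' processing notes name GCOS 1.3. The signal algorithm, its scaling target, detection calls and any filter are not given in the sources used here. The deposited values are linear intensity signals per probe set, all positive, and every array's mean after trimming 2% at each end lay between 1494 and 1496, so that each array had been scaled by a factor of its own. The array medians still differed 2.1-fold, from 526.8 to 1103.9. The table held 45037 probe sets and no control probe sets. A probe annotation gave 1 gene symbol for 34945 of them and several for 932, and 9160 are unnamed here. Symbols were updated through gene IDs in the RefSeq table of assembly GRCm38.p6, which matched 34741 of the single-gene probe sets. Probe sets with several symbols were tested but not named, and no coordinates are given because the build behind the array annotation is not given in the sources used here.

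The design, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The plan was to use the deposited table as scaled unless array medians differed by over 1.5 times, in which case it was to be quantile normalized. That condition was met, so the values were transformed to log2(signal + 16) and quantile normalized. Fold changes are on this scale, which understates changes of dim probe sets. Probe sets at or above the 40th percentile of mean log2 signal were kept, leaving 27022 probe sets and 13702 named genes. Group means of all 9 arrays were fitted together in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with a variance trend), with contrasts MC minus YC, CR minus MC and CR minus YC and a moderated F test over the 3 groups. Benjamini-Hochberg adjusted p under 0.05 was the threshold. Standard errors (SE) come from this fit. The number of arrays limits the precision: the median SE of a log2 change was 0.43, and 3 pools per group sample only a few mice.

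Gene lists for cochlear cell types, for other cells and tissues that a dissected inner ear can hold, and for apoptosis, stress, metabolic and clock genes were tested with camera at a preset correlation of 0.01. There were 32 lists with at least 5 measured genes, and p was adjusted over the lists. Each gene was represented by its brightest single-gene probe set. Camera with an estimated correlation and fry were run beside it. Tests were run on simulated data of 27022 probe sets with independent normal noise of each probe set's own spread and no array classes. For age they recovered 8%, 40%, 66% and 86% of 50 probe sets each changed by 1, 2, 3 and 4 log2 units. For calorie restriction the shares were 6%, 28%, 60% and 76%, again of 50 each among 27022 probe sets.

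Named genes were chosen as follows. Where at least 5 genes of a direction passed the threshold with no overlap between the groups, the 12 with the largest change were taken. Where fewer did, the 6 genes with the smallest p and no overlap were taken. Each list contributed up to 4 members past the threshold, or else the 2 with the smallest p, and a short set of fixed genes could be named whatever their values. Malat1 in the calorie restriction comparison and Tnnc2, Acta1, Zic1, Calb1, Camk2a, Mobp and Aqp4 in the closing section, as abundant members of their lists, were chosen after their values were seen.

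Alternatives chosen beforehand were a pseudocount of 1 or 64, no signal filter or one at the 60th percentile, centring arrays on their median, no variance trend, array weights, only the compared groups in the fit, the replicate number as a block, each array left out in turn, and for the lists the other tests and the mean of all probe sets of a gene. After the data were seen, the deposited table without quantile normalization, array class as a term, array median as a covariate, and comparisons within each array class were added. Array class divides the 4 arrays with a median signal under 627 from the 5 with a median over 842. The labels give no scan date or batch.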

Results

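The series asked how gene expression in the mouse cochlea differs with age and with long-term calorie restriction. Cochlear RNA of 4-month controls, 15-month controls and 15-month calorie-restricted mice was compared, with 3 pooled samples per group. The 9 arrays fell into classes by median signal that did not follow the groups alone. The 3 calorie-restricted arrays and young control 1 had median signals between 526.8 and 626.6, and the 3 older controls and young controls 2 and 3 had medians between 842.4 and 1103.9. After quantile normalization, pairs of low-median arrays correlated at r = 0.883 to 0.911 and pairs of high-median arrays at 0.771 to 0.861. Pairs across the classes correlated at 0.661 to 0.847, a range that overlaps that of the high-median pairs. All restricted arrays were low-median and all older controls high-median, and only the young controls spanned both. Without quantile normalization the median log2 change over all probe sets was 0.10 for age and -0.31 for calorie restriction. After normalization it was 0.02 for both.

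**Figure D1:**
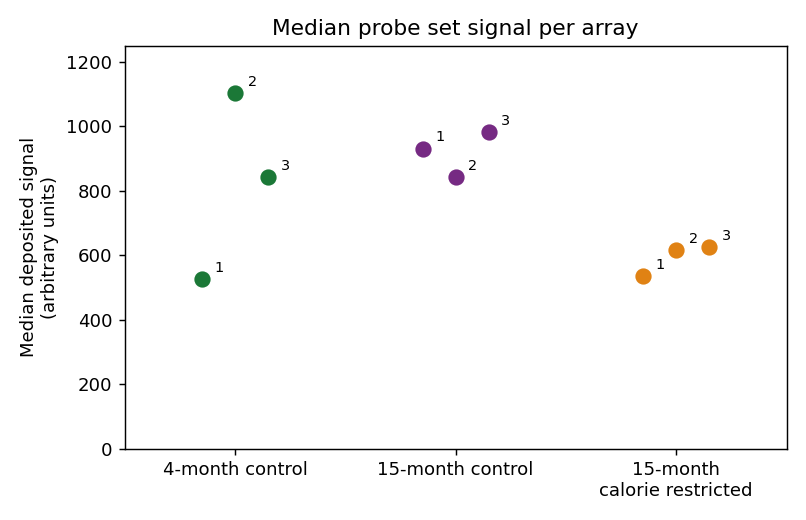
Median deposited signal of each of the 9 arrays in arbitrary units, by group, 1 point per array with its replicate number. The 3 restricted arrays and young control 1 lie at or below 626.6, and all other arrays lie at or above 842.4.

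The first comparison asked what changed between 4 and 15 months of age. No gene passed the threshold, and 3 of the 32 lists were called with the preset correlation. With an estimated correlation each of these had an adjusted p of 0.986, and with fry 0.982. Skeletal muscle genes rose in the older controls, with 28 of 28 measured members higher and a median log2 change of 0.37 (camera, adjusted p = 2.74e-06). Spiral ganglion neuron genes, markers of the neurons that carry sound signals to the brainstem, rose as well, with 26 of 33 members higher and a median of 0.27 (adjusted p = 0.00197). Brain tissue genes fell, with 15 of 23 members lower and a median of -0.31 (adjusted p = 0.0162). By array median, young control 3 (0.96) lay above older controls 1 (0.91) and 2 (0.45) in the muscle list. In the brain list young controls 2 (-0.44) and 3 (-0.17) lay below older control 1 (-0.15), and in the neuronal list the groups did not overlap.

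Within the muscle list, Myh2, a fast myosin heavy chain, had a log2 change of 1.22 ± 0.43 (SE) and Xirp1, an actin-binding protein of striated muscle, 1.11 ± 0.36. Among neuronal genes, Prph, a neuronal intermediate filament, changed by 0.97 ± 0.35 and Cplx1, a regulator of synaptic vesicle release, by 0.50 ± 0.19. Among brain genes, Car8, abundant in Purkinje cells, changed by -1.12 ± 0.46 and the transcription factor gene Zic2 by -1.33 ± 0.76. None of these 6 genes passed by itself. With array class as a term, the muscle median was 0.12 and the brain median -0.28, neither called (adjusted p = 0.466 for each), and the neuronal list kept its call (median 0.26, adjusted p = 0.0141). Of 25 alternatives, the muscle call held in 18, the neuronal call in 20 and the brain call in 13. The neuronal call was lost with arrays centred on their median, in the table as deposited and without older control 2. The muscle call was lost without older control 3 or young control 1, and the brain call without any 1 of the restricted arrays, older control 2 or 3 or young control 1. The heat shock list, with Cryab at 0.70 ± 0.26 and Hspa8 at 0.36 ± 0.15, was called with that term (adjusted p = 0.0141) and not without it (adjusted p = 0.16).

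At the level of single genes, 0 of 27022 probe sets passed in limma, and 915 had an unadjusted p under 0.05, 367 higher and 548 lower in older mice. The smallest adjusted p was 0.927. The groups did not overlap for 5.88% of probe sets, where chance gives 10%. The genes with the smallest p and higher values at 15 months were Smad2, a mediator of TGF-beta signalling (log2 change 2.22 ± 0.45), Ptbp1, a splicing regulator (1.10 ± 0.26), and the transcription factor gene Zic5 (1.96 ± 0.46). They also included Ern1, a sensor of unfolded proteins (1.82 ± 0.45), the mitochondrial isocitrate dehydrogenase gene Idh2 (0.70 ± 0.18) and the sulfiredoxin gene Srxn1 (1.80 ± 0.46). On the lower side stood Adal, an adenosine deaminase-like gene (-3.20 ± 0.50), and Akr1c18, which encodes a hydroxysteroid dehydrogenase (-2.33 ± 0.37). Aard (-2.90 ± 0.52), Cklf (-2.80 ± 0.58), Tti2 (-2.38 ± 0.49) and Ubxn2a (-1.64 ± 0.35) completed these 12 genes, none of them past the threshold. Of the age genes named in the text, 20 had several probe sets, and in 17 of these at least 1 other probe set had the opposite sign. Hair cell markers were not called (adjusted p = 0.953): 9 of 13 measured members were higher, and the members with the smallest p were Rasd2 at -0.76 ± 0.36 and Myo7a, an unconventional myosin of hair cells, at -0.81 ± 0.40. Only 13 of the 40 genes of this list were measured past the signal filter, so the missing call says little about hair cells.

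The second comparison asked how restriction from 2 to 15 months of age changed the cochlea. Transcripts of skeletal muscle were lower in the restricted samples. Among the called genes the largest fall was in Myh2, which was 19.9-fold lower (log2 change -4.31 ± 0.43 SE, n = 3 per group, limma adjusted p = 0.0233). Of the 22 named genes past the threshold, 21 were lower, and 14 of the 22 belonged to the skeletal muscle list. In total 25 of 27022 probe sets passed, 1 higher and 24 lower.

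After Myh2 came Xirp1 (-2.87 ± 0.36, adjusted p = 0.0357), Tpm2, a tropomyosin (-2.56 ± 0.38, adjusted p = 0.0455), and Csrp3, a LIM protein of the sarcomere (-2.54 ± 0.32, adjusted p = 0.0357). Pygm, the muscle glycogen phosphorylase, fell by 2.52 on the log2 scale, Tcap, the titin cap protein, by a log2 change of -2.48, and the stress-responsive muscle gene Ankrd2 by one of -2.42. The sarcoplasmic calcium-binding protein gene Casq1 changed by -2.41, the muscle cytochrome oxidase subunit gene Cox6a2 by -2.35, and the myoglobin gene Mb by -2.33. Lmod2, an actin nucleator of muscle, changed by -2.28 and Tnni2, fast troponin I, by -2.22. The calcium pump gene Atp2a1 (-1.95 ± 0.25) and the muscle enolase gene Eno3 (-2.13 ± 0.28) were called with an adjusted p of 0.0357 each. All 25 called probe sets separated the groups without overlap, as did 37.8% of all probe sets, where chance gives 10%.

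**Figure D2:**
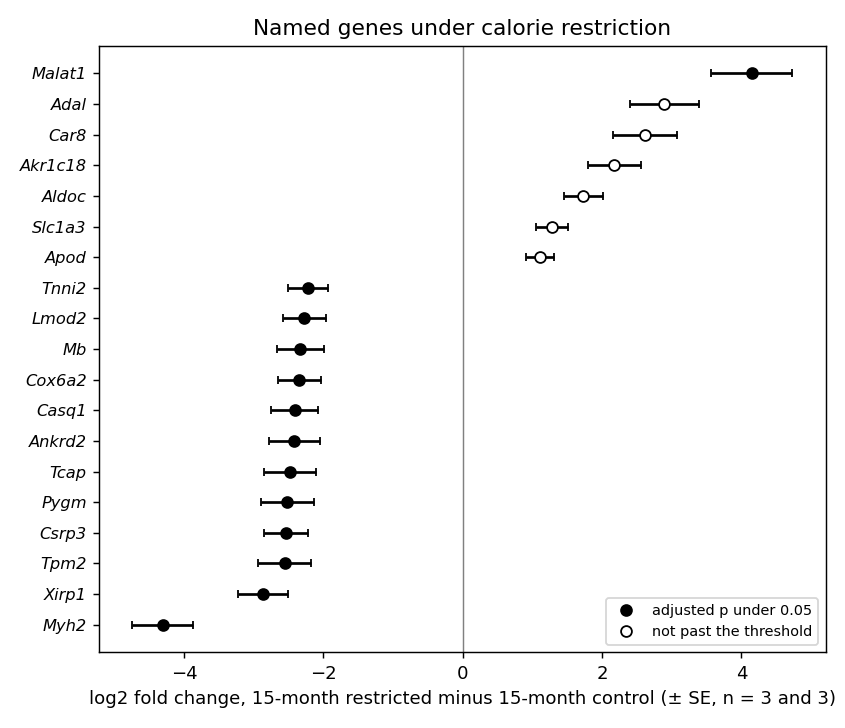
Log2 fold change of named genes between calorie-restricted and control mice of 15 months, as points with SE bars and 3 samples per group. Filled points passed an adjusted p of 0.05, and the open ones did not. The 12 named lower genes lie between -4.31 and -2.22.

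The only called gene with higher values in restricted samples was Malat1, a long non-coding RNA of the nucleus, by 1 of its 6 probe sets (4.15 ± 0.59, adjusted p = 0.0441). It was chosen after its values were seen, and the other probe sets gave log2 changes from -0.37 to 1.76, none called. On the called probe set the restricted arrays spread widely, with deposited signals of 4612, 33430 and 10902. The SD of its log2 values was 1.44 in restricted and 0.05 in older control samples. The genes with the next smallest p were Aldoc, a brain form of aldolase (1.73 ± 0.28, adjusted p = 0.0616), Akr1c18 (2.18 ± 0.37, adjusted p = 0.0795), Adal (2.89 ± 0.50, adjusted p = 0.0795) and Car8 (2.61 ± 0.46, adjusted p = 0.0804). Slc1a3, a glutamate transporter of glia and supporting cells (1.28 ± 0.23), and Apod, an apolipoprotein (1.11 ± 0.20), each had an adjusted p of 0.0841. The 3 probe sets of Car8 disagreed, with log2 changes from -1.22 to 2.61. The count of called probe sets was 0 with array class as a term, with the array median as a covariate, with arrays centred on their median and without a variance trend. It was also 0 without restricted replicate 2 or 3 or older control 1 or 3. It was 1147 without young control 2, 209 without young control 1, 49 without older control 2 and 2 without restricted replicate 1, and the muscle list was called in each of these fits.

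Of the 32 lists, 15 passed in the calorie restriction comparison with the preset correlation, 0 with an estimated correlation and 2 with fry. All 28 measured skeletal muscle genes were lower, 13 of them past the threshold by their brightest probe set and 28 when adjusted over the list alone, with a median log2 change of -2.04 (adjusted p = 4.37e-36). With an estimated correlation of 0.519 between members the adjusted p = 0.25, with fry it was 0.014, and with array class as a term the median was -1.45 (adjusted p = 1.23e-22). Brain tissue genes rose, with 21 of 23 members higher, 0 of them past the threshold and 11 when adjusted over the list alone, and a median of 1.11 (adjusted p = 1.09e-07). Their adjusted p = 0.25 with an estimated correlation and 0.0251 with fry. Gng13, a G protein subunit of taste and Purkinje cells, changed by 4.72 ± 1.08 in this list, by 1 of 2 probe sets.

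Several lists of cochlear cell types rose in the restricted samples, and each lost its call with array class as a term or an estimated correlation. Fibrocyte genes of the spiral ligament and limbus were higher in 16 of 20 cases with a median of 0.64 (adjusted p = 0.000712), among them Otos, an otospiralin (1.04 ± 0.25), and Coch, cochlin of the cochlear matrix (0.98 ± 0.26). Supporting cell and tectorial membrane genes were higher in 17 of 22 cases with a median of 0.78 (adjusted p = 0.00152), with Slc1a3 above and Sparcl1 at 1.19 ± 0.26. Genes of the stria vascularis, which secretes endolymph, were higher in 12 of 18 cases with a median of 0.54 (adjusted p = 0.033), among them Kcnj10, its potassium channel (1.76 ± 0.42), and Cldn11, a claudin of its basal cells (1.89 ± 0.47). With array class as a term the adjusted p = 0.161, 0.259 and 0.161 for these lists, and with an estimated correlation it was 0.461, 0.441 and 0.441. The gap junction gene Gjb6 changed by 1.06 ± 0.25 (adjusted p = 0.146). Spiral ganglion neuron genes rose in 22 of 33 cases with a median of 0.25 (adjusted p = 0.033, and adjusted p = 0.461 with an estimated correlation), with Snap25 at 1.73 ± 0.32 and Vsnl1 at 1.23 ± 0.26, both of the nerve terminal or its calcium signalling. By array median, restricted 1 (0.09) lay below older control 2 (0.26) in the neuronal list. Of 24 alternatives, the call held in 21 for fibrocyte, 21 for supporting cell, 13 for stria vascularis and 15 for neuronal genes. Brain tissue genes rose in the same samples. Whether brain tissue rather than cochlear cells gave the higher values of genes that both can express was not tested. Hair cell genes were not called (adjusted p = 0.773, 7 of 13 higher), with only 13 of 40 list genes measured past the filter.

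Lists of 4 blood or immune cell types and the cell cycle list fell, and the B cell and plasma cell list was not called (adjusted p = 0.294). Neutrophil and myeloid progenitor genes were lower in 18 of 22 cases (median -0.44, adjusted p = 0.00389), including the granule protein gene Ngp (-0.75 ± 0.23) and the oxidase subunit gene Ncf1 (-0.85 ± 0.28). Macrophage genes were lower in 23 of 29 cases (median -0.33, adjusted p = 0.00389), including the surface markers Adgre1 (-0.97 ± 0.23) and Trem2 (-2.41 ± 0.63). Erythroid genes were lower in 17 of 19 cases (median -0.37, adjusted p = 0.00943), including the band 3 gene Slc4a1 (-0.84 ± 0.23) and Rhd (-0.74 ± 0.32). Cell cycle genes were lower in 26 of 32 cases (median -0.33, adjusted p = 0.00935), including Ccna2 (-0.998 ± 0.25) and Mcm2 (-0.92 ± 0.27). With an estimated correlation these 4 lists had an adjusted p of 0.51, 0.461, 0.648 and 0.558 in that order. With array class as a term they kept their calls at the preset correlation, with medians from -1.16 to -0.77. Across arrays, the interval of each mean list score difference with that term ran from a negative to a positive value. It was -2.09 to 0.16 for neutrophil, -1.55 to 0.04 for macrophage, -2.53 to 0.55 for erythroid and -1.87 to 0.13 for cell cycle genes. The erythroid and macrophage calls were lost with arrays centred on their median, and the erythroid and cell cycle calls without restricted replicate 3 or older control 2. By array median, restricted 1 (0.08 for erythroid, 0.12 for cell cycle genes) lay above older control 1 (-0.04, 0.03). For neutrophil and myeloid progenitor genes, restricted 1 (0.02) lay above older control 3 (-0.16). T cell and NK cell genes were lower in 12 of 13 cases (median -0.63, adjusted p = 0.0127), including Bcl11b (-0.76 ± 0.28) and Klrd1 (-1.04 ± 0.41). Their adjusted p = 0.265 with an estimated correlation and 0.976 with array class as a term, and their call held in 16 of 24 alternatives.

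Among matrix and metabolic genes, collagen and extracellular matrix genes fell in 24 of 33 cases (median -0.28, adjusted p = 0.0039), including the collagen chaperone gene Serpinh1 (-1.09 ± 0.24) and Col6a1 (-0.66 ± 0.20). Adipocyte genes rose in 19 of 20 cases (median 0.51, adjusted p = 0.000302), including Ucp1, the uncoupling protein of brown fat (1.01 ± 0.21), and Gpd1 (0.84 ± 0.24). Glucocorticoid response genes rose in 19 of 23 cases (median 0.49, adjusted p = 0.00935), where the metallothionein gene Mt2 changed by 1.09 ± 0.20 and the pyruvate dehydrogenase kinase gene Pdk4 by -0.82 ± 0.21. Fatty acid synthesis genes rose in 17 of 22 cases (median 0.34, adjusted p = 0.0371), including Tkt (0.67 ± 0.26) and the desaturase gene Fads2 (1.20 ± 0.46). With an estimated correlation these 4 lists had an adjusted p of 0.441, 0.461, 0.461 and 0.558 in that order, and only the adipocyte list among them was called with array class as a term (adjusted p = 0.000854). Across arrays, the interval of the adipocyte mean list score difference with that term ran from -1.07 to 1.57. Of 24 alternatives, the call held in 18, 22, 19 and 11, in the same order. The fatty acid synthesis call was lost on leaving out restricted replicate 2 or 3, any older control or young control 2. By array median, restricted 1 (-0.04) lay below older controls 1 (-0.02) and 2 (0.05) in that list. No single gene named in the cochlear, blood, immune, matrix or metabolic lists passed the threshold. With arrays centred on their median in place of quantile normalization, Ngp, Col6a1, Slc4a1 and Pdk4 turned to positive changes of at most 0.28. Of the restriction genes named in the text or the closing section, 27 had several probe sets, and in 8 of these at least 1 had the opposite sign.

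**Figure D3:**
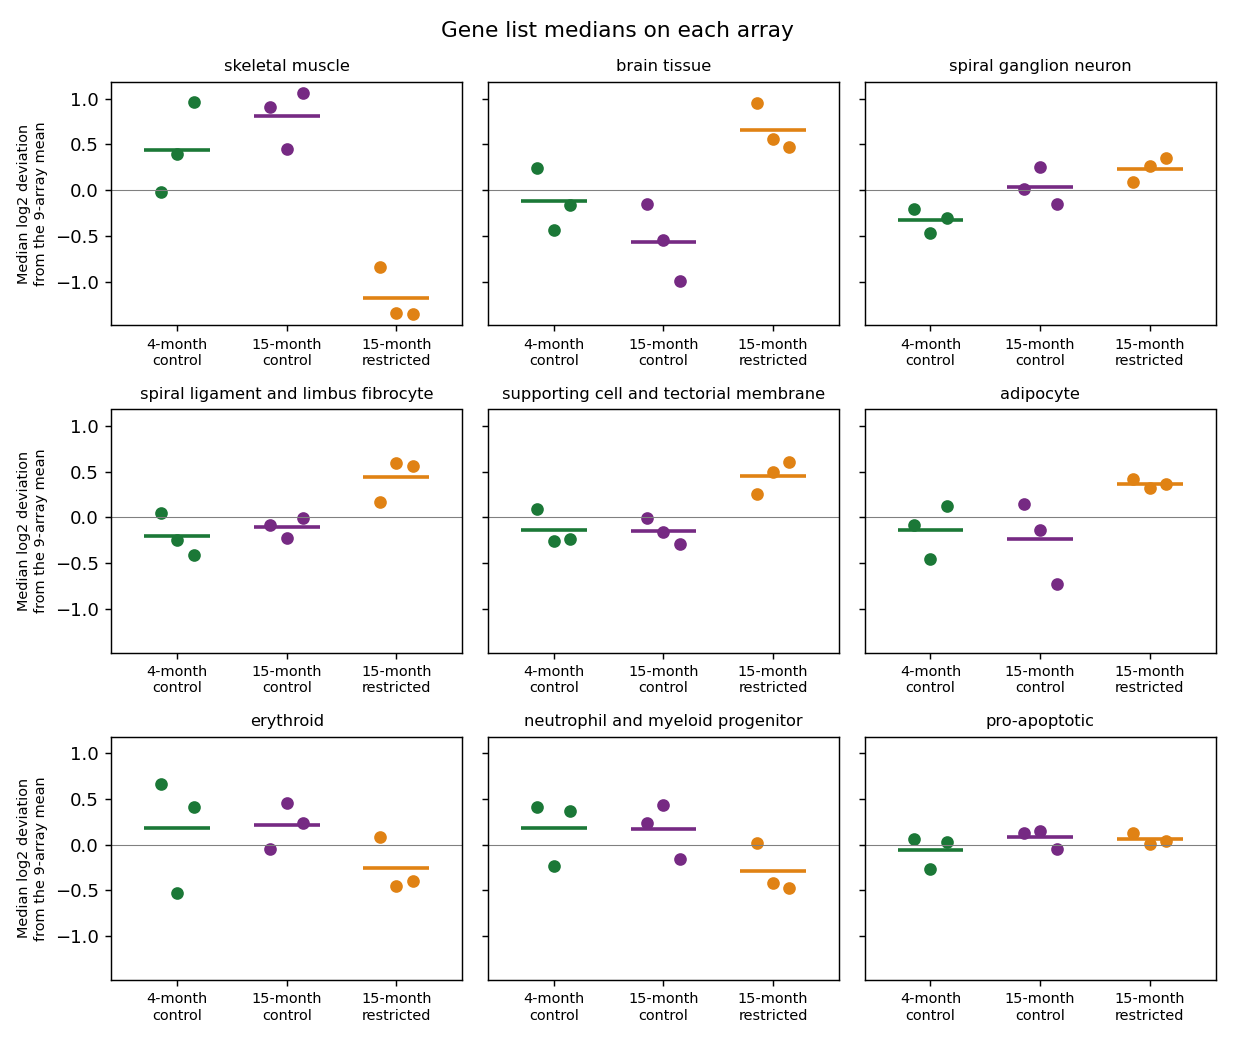
Median log2 deviation of the measured genes of 9 lists from their mean over the 9 arrays, 1 point per array, with the mean of each group as a line. Skeletal muscle genes lie between -1.35 and -0.84 on the restricted arrays and at or above -0.02 on the others, and the pro-apoptotic genes show no such separation.

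Apoptosis genes are named in the title of the series, and neither of their lists was called in either comparison. Of 41 measured pro-apoptotic genes, 22 were higher at 15 months (median log2 change 0.09, adjusted p = 0.971) and 22 were higher under restriction (median 0.09, adjusted p = 0.739). Of 30 anti-apoptotic genes, 16 were higher with age (adjusted p = 0.953) and 20 under restriction (median 0.20, adjusted p = 0.324). In the table as deposited the anti-apoptotic list was called up under restriction (adjusted p = 0.0426), and with array class as a term its median was -0.33 (adjusted p = 0.161). No member passed by itself, whether adjusted over all probe sets or adjusted over the list alone. With age, Casp12, an endoplasmic reticulum caspase, changed by -0.78 ± 0.33 and Hrk, a BH3-only gene, by 0.66 ± 0.37. Bak1, which encodes a pore-forming protein of the mitochondrial outer membrane, changed by 0.47 ± 0.51 with age and by -0.10 ± 0.51 under restriction (adjusted p = 0.921). Bcl2l11, which encodes the BH3-only protein Bim, changed by 0.23 ± 0.34 with age and by -0.94 ± 0.34 under restriction (adjusted p = 0.21). In the restriction comparison 2 of the 4 probe sets of Bcl2l11 had the opposite sign, and with array class as a term its change was -0.05. The death ligand gene Tnfsf10 changed by -0.87 ± 0.39 under restriction (adjusted p = 0.263).

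The remaining contrast set restricted mice of 15 months against young controls, a comparison that the series text does not name. No probe set passed (2910 had an unadjusted p under 0.05 in limma, and the smallest adjusted p was 0.16). With the preset correlation 14 lists were called, with an estimated one 0 and with fry 2. All 28 skeletal muscle genes were lower than in young controls (median -1.55, adjusted p = 4.82e-35), spiral ganglion neuron genes were higher in 29 of 33 cases (median 0.47, adjusted p = 5.51e-07) and brain tissue genes in 20 of 23 (median 0.99, adjusted p = 2.92e-05). With an estimated correlation the adjusted p = 0.205, 0.205 and 0.238. Over all 3 groups, the moderated F test called 0 probe sets, with 3226 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0697.

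Age and restriction changes were negatively correlated over 13702 genes, although the neuronal list was higher in both, with a covariance of -0.18 and a Pearson r of -0.502 across genes, which are not independent replicates. Both comparisons share the 3 older control arrays with opposite sign, and simulated unchanged groups gave a covariance of -0.14 and an r of -0.553. The observed covariance differed from the simulated one by -0.05. Leaving out 1 array moved the observed covariance between -0.36 (without young control 2) and -0.02 (without young control 1). It was -0.34 without older control 2 and -0.34 with array class as a term. Akr1c18 and Adal were named in both comparisons for their small p, a choice that with shared older controls favours low values there. The mean log2 signal of Akr1c18 was 10.58 ± 0.37 (SD, n = 3) in young, 8.25 ± 0.21 in older and 10.42 ± 0.17 in restricted mice, and that of Adal 10.19 ± 0.61, 7.0 ± 0.24 and 9.89 ± 0.30. As 0 probe sets passed for age, 0 could be counted as turned back under restriction.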

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

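The deposited table without quantile normalization, array class, array median and the within-class fits were added after the data were seen. The age comparison gave 0 probe sets under all 22 alternatives that fitted it, with 372 to 2696 at an unadjusted p under 0.05. The restriction count of 25 fell to 0 with arrays centred on their median, without a variance trend, with array class as a term and with the array median as a covariate, and to 7 in the table as deposited (1 higher, 6 lower). It was 3397 with array weights (1793 higher, 1604 lower) and 1846 with only the compared groups (771 higher, 1075 lower), and these kept all 25 probe sets. The class term raised the median SE from 0.43 to 0.71: Myh2 went from -4.31 ± 0.43 to -4.24 ± 0.82, and Tnni2 from -2.22 ± 0.29 to -1.33 ± 0.43. With only the compared groups the fold changes were the same by design (muscle list median -2.04). That count rose through the error estimate alone, which then left out the young arrays. With array weights, the young arrays had weights of 0.25 to 0.55 and the restricted arrays 2.78 to 4.33. For the remaining settings the cause was not tested. Leaving out 1 array gave 0 to 1147 restriction probe sets, 0 to 328 for restricted against young (328 without young control 1), 0 to 50 over any group (50 without young control 1, 35 without young control 2, 15 without older control 2, 8 without young control 3), 1 to 4 age lists (1 without older control 2 or 3) and 10 to 16 restriction lists. The count over any group was 1 without a filter, 1 in the table as deposited and 1027 with array weights. Low-median arrays gave 4 probe sets for restricted against young control 1 alone, assumed to vary like the others, so that array cannot be told from its group. The age lists fell to 0 with an estimated correlation and with fry, and the restriction lists to 0 and 2.

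Replicate numbers did not pair the samples, with correlations of same-numbered deviations from -0.29 to 0.27 and 3 of 9 arrays closest to their own number. With the replicate block 0 restriction probe sets passed, and the age count was 0. Of 1987 values of named genes under the alternatives, 1975 kept their direction. This count is no measure of robustness, since many values could not turn. Dropping the variance trend, fitting only the compared groups and the replicate block leave a fold change as it was. Leaving out an array of the group not compared hardly moves it, and many of these genes were chosen for their change or p in the same data. With arrays centred on their median, the restriction change was 0.19 for Ngp, 0.28 for Col6a1, 0.0848 for Slc4a1, 0.12 for Pdk4, 0.028 for Bak1, 0.0631 for Ppp1r15a and 0.0446 for Camk2a. For Aqp4 it was -0.0586 with array class as a term. The age change of Bcl2l11 was -0.0683 with array class as a term and -0.0666 among high-median arrays, and leaving out 1 array gave -0.067 (without young control 1) to 0.59. That of Bak1 ran from -0.12 (without young control 2) to 0.86. The cause was not tested. No background measure was used here, so signal over background cannot be given.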

Other observations

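Neither the clock list nor the fatty acid oxidation list was called, and none of their members named here passed the threshold. Only in the table as deposited was the fatty acid oxidation list called up under restriction (adjusted p = 0.0227). Dbp, an output gene of the circadian clock, had a log2 change of -0.98 ± 0.36 (SE) with age and Per2, a core clock gene, one of 0.76 ± 0.32. Under restriction the clock repressor genes Nr1d2 and Ciart changed by 1.09 ± 0.31 and 1.09 ± 0.42, with 14 of 19 clock genes higher (adjusted p = 0.394). Among fatty acid oxidation genes, the peroxisomal enzyme gene Ehhadh changed by 1.67 ± 0.38 and Pdk4 by -0.82 ± 0.21 (list adjusted p = 0.473). Among oxidative phosphorylation genes, 33 of 56 were higher (adjusted p = 0.658), with Uqcrh of complex III at 0.75 ± 0.16. With array class as a term this list was called (adjusted p = 0.00101, median 0.20), while the interval of its mean list score difference ran from -0.22 to 0.52.

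Lists of stress genes were not called in the restriction comparison, and none of the members named here passed. With array class as a term the unfolded protein response list was called down (adjusted p = 0.0387, median -0.42), as was the heat shock list (adjusted p = 0.00564, median -0.41). The intervals of their mean list score differences with that term ran from -1.56 to 0.65 and from -1.14 to 0.18. Atf3, a stress transcription factor gene, changed by -1.71 ± 0.52 and Ppp1r15a, which restores translation after stress, by -0.73 ± 0.23, in an unfolded protein response list with 16 of 28 members higher (adjusted p = 0.761). Ier2, an immediate early gene, changed by 1.29 ± 0.32 in a list with 18 of 22 members higher (median 0.35, adjusted p = 0.127). That list was called up in 6 of 24 alternatives, and with array class as a term its median was -0.19 (adjusted p = 0.397). Ibsp, a matrix protein of bone, changed by -1.55 ± 0.59 with age and 1.58 ± 0.59 under restriction, by 1 of 2 probe sets, and these contrasts share the older controls. Of the remaining lists, myelin, B cell, p53 target, antioxidant, heat shock, interferon, cholesterol synthesis and cytosolic ribosome genes had adjusted p values from 0.16 to 0.978 with age and 0.294 to 0.773 under restriction, and bone genes 0.715 and 0.473. Under restriction the myelin and B cell lists were called in 2 of 24 alternatives each and the antioxidant list in 1, and with age the heat shock list in 4 of 25. For hair cell and unfolded protein response genes under restriction the median log2 changes were 0.38 and 0.04 while the test pointed down. With age the test pointed down for erythroid, adipocyte and interferon genes, with medians of 0.02, 0.02 and 0.05, and up for antioxidant genes, with a median of -0.01.

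The tests of the muscle and brain patterns below were chosen after those patterns were seen, while the test across genes on array class and the splits were set before their results. The first pattern is the fall of 28 skeletal muscle genes in restricted samples, whose mean list score differed by -2.08. With array class as a term the difference was -1.56, with a 95% interval from -2.97 to -0.14. This argues only weakly against array class as its whole cause. Class was estimated from the 3 young arrays alone, with young control 1 as the only low-median array among them. A candidate explanation is that muscle tissue attached to the dissected bone was carried over in different amounts, and the deviations of the 28 genes inside groups had a mean pairwise correlation of 0.519, where 95% of 1000 random lists matched on signal lay below 0.0757. None of the other 31 lists reached this value, and the highest of them had 0.437. The members with the highest mean signal, Tnnc2, Acta1 and Atp2a1, were at mean log2 signals of 17.30, 17.02 and 17.08 in older controls and 15.49, 15.15 and 15.12 in restricted samples, and 0 of the 28 are in another list. The changes ran from -4.31 to -1.21, and Myh2 fell by 2.32 ± 0.46 (SE) more than the mean of the other members (adjusted p = 0.02). A single shift in amount would not give this if the signals of all members followed the amount alike, which was not tested. At an unadjusted p under 0.05, 5 of 28 members departed from the others. A joint change of expression inside muscle fibres would give the same correlation, and an effect of the diet itself was not tested, so both stay open.

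The second pattern is the extent of differences between restricted samples and older controls, with 18.5% of probe sets at an unadjusted p under 0.05. Young control 1, a low-median array, minus young controls 2 and 3 correlated with the restriction change across 13702 genes at r = 0.648, although these comparisons share no array. The sign was the same for 74.4% of genes, and r was 0.65 without the muscle and brain genes. Young control 2 had the highest median signal and the lowest mean correlation with the other arrays (0.732). How far it alone carried this r was not tested. By array median, young control 1 also lay below young controls 2 and 3 in the muscle list (-0.02 against 0.39 and 0.96). In the brain list it lay above them (0.24 against -0.44 and -0.17), and restricted samples differed from older controls in the same directions. A difference in RNA, labelling, hybridisation or tissue content that goes with the array classes may therefore account for part of the change. These cannot be told apart here, and no restricted sample lies in the high-median class to separate them from the diet.

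The third pattern is the rise of brain tissue genes in restricted samples, by 1.51 in the mean list score. A lower share of muscle alone would raise all other tissues alike, yet the brain list moved away from the erythroid list by 1.86 (95% interval 1.23 to 2.49). This argues against it as the whole cause. The erythroid list itself fell by 0.35 in the mean list score, while the adipocyte, fibrocyte and supporting cell lists rose by 0.57, 0.56 and 0.60. A lower muscle share as a part of the brain rise was therefore not excluded. For brain tissue carried over in different amounts the test decides nothing: inside groups the 23 genes had a mean correlation of 0.122 against 0.0954 at the 95th percentile of random lists, but 18 of the other 31 lists were as high. Of the 5 members with the highest mean signal, Zic1 (13.39 against 11.84), Calb1 (12.75 against 11.78), Mobp (12.47 against 11.36) and Aqp4 (12.01 against 10.99) had higher mean log2 signals in restricted samples than in older controls and Camk2a a lower one (11.42 against 12.14), and 0 of the 23 are in another list. The Camk2a change of -0.71 depended on single arrays: it was -0.10 without older control 3 and -1.25 without older control 2. At an unadjusted p under 0.05 in limma, 6 of 23 members departed from the mean of the others, 0 of them past the threshold. They departed in both directions, with Gng13 at 3.36 ± 1.08 (SE) and Camk2a at -2.32 ± 0.67 against the other members. Carried-over brain tissue, array class and the diet stay open, since the difference was 0.74 with class as a term and its interval from -0.36 to 1.84 held both 0 and the full difference.

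Other splits of the samples were counted for each result. With 10 splits of 6 arrays no share under 0.05 can be reached. The restriction split gave 25 probe sets and 15 lists, 1 of 10 splits as large in each case, and the highest other splits gave 0 and 13. The age split gave 3 lists, which 6 of 10 reached, with 5 as the highest other. Where the real count was 0, every split is as large by construction, so that 10 of 10 for age, 10 of 10 for restricted against young and 100 of 100 drawn from 280 for the test over any group decide nothing. The highest other splits of these gave 117, 0 and 1785 probe sets. The split with 1785 kept the restricted arrays together and set older controls 1 and 3 with young control 2 apart from older control 2 with young controls 1 and 3. In it, 4758 probe sets separated the restricted arrays from the first of these sets, 3 from the second, and 117 the control sets from each other. This split was picked for its count. Its control sets also divide by median signal. The first set had medians of 931.1, 981.3 and 1103.9, and the second had 843.6, 526.8 and 842.4, nearer to the restricted arrays. The split thus follows median signal among the controls, and what lies behind that signal was not tested.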
